A study of Homo sapiens with 6 samples.

How the data were processed

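RNA from 6 cultures of passage 3 human dermal microvascular endothelial cells was measured on Affymetrix expression arrays, 3 untreated and 3 treated with BMP9. Per the labels' protocols, cells were kept in EGM-2-MV medium with 1% fetal bovine serum at 37 °C and 5% CO2, BMP9 at 5 ng/ml was added after 24 h of culture, and cells were harvested 24 h later. Total RNA was extracted with Trizol and biotinylated cRNA was made from 5 µg of total RNA, per the labels' protocols, while another label speaks of polyA+ RNA. Each culture gave 1 array.

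The deposited values are linear intensities, 1 per probe set, as the authors processed them. The mean intensity after dropping the lowest and highest 2% of probe sets was about 150.02 on each array, so the deposited arrays look scaled to a common target. The summarisation software and the scaling step are not given in the sources used here. The number of arrays limits the precision of every comparison, and no depth applies to arrays.

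The table holds 54675 probe sets, of which 62 controls were left out and 54613 were tested. Gene names came from the platform's annotation, updated through Entrez identifiers with RefSeq genes of GRCh38.p14, used for names only. Of 41097 probe sets with 1 identifier 41043 matched, and 0 symbols changed. There were 41091 probe sets with 1 gene, 1801 with several, from which no gene was named, and 11721 not listed in the annotation, which are unnamed here. A gene was represented by the probe set with the highest mean over the 6 arrays among those annotated to that gene alone, which gave 19775 genes. Of the 85 genes held in the tables for naming, 46 had several probe sets and 22 had at least 1 probe set whose difference had the opposite sign, among them ACVRL1, BMPR2, SMAD6, PECAM1, MSX1, PDGFRA, ACKR3, KCNMA1 and CXCL2.

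Values were analysed as log2(intensity + 16), so the fold changes of dim probe sets are understated. Arrays were used as deposited because their log2 medians, 5.33 to 5.63, differed by less than 0.5, the limit set beforehand for quantile normalization. BMP9-treated and untreated cultures were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 variance prior for all probe sets, no covariate), with Benjamini-Hochberg adjustment over all 54613 probe sets and a threshold of 0.05. SE is limma's moderated standard error from this fit throughout, also where the adjusted p is that of the fit whose prior follows intensity. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

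Before the data were examined, 30 gene lists, the rule for naming genes and the alternatives were fixed. The lists covered BMP-SMAD targets, TGF-beta superfamily members, Notch, chemokines, inflammatory activation, VEGF, PDGF and angiopoietin signalling, tip cells, endothelial identity (general, arterial, venous, lymphatic) and markers of fibroblasts, pericytes and smooth muscle, keratinocytes and leukocytes. They also covered the cell cycle (mitotic and S phase genes, cyclin D and CDK inhibitors), endothelial-mesenchymal transition, matrix, proteases, vasoactive factors, flow-responsive KLF genes, YAP-TAZ and SRF targets, interferon, stress, cholesterol synthesis, hypoxia, guidance, oxidative phosphorylation and ribosomal proteins. Of 500 distinct list genes 34 had no probe set of their own here. Several genes stand in more than 1 list, such as CXCR4 in the chemokine, tip cell and arterial lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the arrays and with fry, which asks whether a list's members move, on balance, one way. Members were also counted with p adjusted over the list alone, in the fit with 1 prior unless the intensity-dependent prior is named. Such a p takes no account of the other lists or of the use of more than 1 prior.

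The naming rule took up to 12 genes per direction among those past the threshold, with separated groups and a mean above the median intensity. It also took, per list, up to 4 members past the threshold, or with none the 2 with the largest difference, and ENG, BMPR2, ACVRL1, ID1, SMAD6, SMAD7, CXCL12, CXCR4, CDH5 and PECAM1 in any case. No gene passed the threshold, so only the last parts of the rule applied. The 7 further genes called with the intensity-dependent prior, and ACKR3, CXCL1, CXCL3, CXCL6, CXCL8, ESM1, ID2, ID3, IL6, INHBA, PTX3, LTB, MGP, THBS1, ID4, TMEM100, TNFAIP3 and UNC5B, were chosen after their values were seen.

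The alternatives fixed beforehand were quantile normalization, median centring, offsets of 1 and 64, filters on dim probe sets, removal of probe sets ending in _x_at or _s_at, the mean of a gene's probe sets, the replicate number as a block, an intensity-dependent robust prior, array weights, a fold of at least 2, and leaving out each culture in turn. Variants of the fit with the intensity-dependent prior, the brightest quartile of probe sets alone, and the actin or GAPDH 3' to 5' ratio as a covariate were chosen after seeing the data.

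The tests were run on simulated data for this comparison, with 200 of 54613 probe sets changed, 100 by 2-fold and 100 by 4-fold. The changed ones were all drawn from probe sets above the median intensity, so the recovery of dimmer ones was not measured. The fit with 1 prior recovered 0% of the 2-fold and 47% of the 4-fold changes, with 1 false call among 48. The fit with the intensity-dependent robust prior recovered 10% and 59%, with 2 false calls among 71. Of simulated lists over 19775 genes, camera called 2 of 2 shifted by 0.5 on the log2 scale and 0 of 98 without a shift. The simulated noise was independent between probe sets, so these lists held no co-variation. In the data the estimated correlation was 0.036 for the chemokine list and 0.088 for the inflammatory list. The 0 of 98 therefore does not show how often camera calls lists of co-varying genes. Another split of the real arrays gave 2 lists. Lists were then drawn 10 more times on the same simulated noise. There, 20 lists of 18 members shifted by -0.3 without co-variation were called 16 times with the preset correlation and 0 times with an estimated one. Of 280 lists without a shift 1 and 0 were called. All these lists share 1 set of noise values and are not independent simulations.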

Results

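Gene expression was measured in human dermal microvascular endothelial cells (HMVEC-D), primary cells that line the small vessels of the skin, with and without BMP9. BMP9, the product of GDF2, is a circulating ligand of the TGF-beta superfamily that binds ALK1 (encoded by ACVRL1) and BMPR2 on endothelial cells, with endoglin (ENG) as co-receptor. The series holds 3 untreated cultures and 3 cultures given BMP9 at 5 ng/ml for 24 h, 1 array per culture. The labels call the cultures biological replicates and do not say whether they came from separate donors, so the p-values measure the spread between these cultures. Each array gave a linear intensity for 54613 probe sets that are not controls. The array medians ran from 24.3 to 33.5 intensity units. Across probe sets, which are not independent replicates, Pearson's r was 0.942 to 0.956 between arrays of a group and 0.945 to 0.951 between arrays of different groups. The number of arrays limits the precision of every value below.

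The comparison of BMP9-treated with untreated cells asks which transcripts differ after 24 h of ligand. POSTN, which encodes the matrix protein periostin, was 2.85-fold higher with BMP9 (13.27 ± 0.08 against 11.76 ± 0.12 on the log2 scale, SD, n = 3; log2 fold change 1.51, SE 0.20). SEMA3G, a secreted guidance ligand made by endothelium, was 2.96-fold higher (log2 fold change 1.56, SE 0.21, n = 3 per group). SELE, the leukocyte adhesion molecule E-selectin, was 3.77-fold lower (6.95 ± 0.39 against 8.87 ± 0.47, SD, n = 3; log2 fold change -1.91, SE 0.32) and the chemokine gene CCL20 was 3.50-fold lower (6.54 ± 0.12 against 8.34 ± 0.18, SD, n = 3; log2 fold change -1.81, SE 0.21). For each of these 4 genes the 3 BMP9 values lay entirely on one side of the 3 untreated values. None of the 4 passed limma's test with 1 variance prior for all probe sets (adjusted p = 0.561 for each), and all 4 passed when the prior followed intensity.

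No probe set and no gene passed limma's test after Benjamini-Hochberg adjustment over all 54613 probe sets, and the smallest adjusted p was 0.561. At an unadjusted p under 0.05 limma gave 3331 probe sets, 2103 higher and 1228 lower with BMP9, where chance alone gives 2731. Other splits of the same 6 arrays into groups of 3 gave 2495 to 3405 probe sets, so the real count was not the highest. The 3 BMP9 values lay above the 3 untreated values for 3871 probe sets and below them for 2514, together 11.7% of all, where chance gives 10%. Among the 19775 genes, each represented by its brightest probe set, 712 were higher and 470 lower at that level. After each array was centred on its median the split turned to 420 higher and 750 lower, and after quantile normalization to 532 and 601. Centring moved the median log2 fold change of all genes from 0.03 to -0.07, so small differences of either sign rest on the scaling.

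When limma's variance prior was allowed to follow intensity, with robust estimation, 17 probe sets passed the adjusted threshold, 6 higher and 11 lower with BMP9. They named 13 genes, of which POSTN, ALDH1A1, AOX1, KCNMA1, CXCL2, ITGA2 and EFHD2 were chosen after their values were seen. Higher were POSTN (adjusted p = 8.19e-06 in that fit), SEMA3G (adjusted p = 0.000566), the retinaldehyde dehydrogenase gene ALDH1A1 (log2 fold change 1.02, SE 0.25), CXCR4, and CXCL12 by 1 of its 2 probe sets. Lower were SELE (adjusted p = 0.00167), CCL20 (adjusted p = 0.00111), the aldehyde oxidase gene AOX1 (log2 fold change -1.54, SE 0.20), the calcium-activated potassium channel gene KCNMA1 (-1.62, SE 0.23), the neutrophil-attracting chemokine genes CXCL5 and CXCL2, the collagen-binding integrin gene ITGA2 (-1.53, SE 0.35) and EFHD2 (-1.09, SE 0.24). Another POSTN probe set passed as well, at a log2 fold change of 2.01 (SE 0.29). KCNMA1 and CXCL2 each had a dimmer probe set with a difference of the opposite sign, at 0.29 and 0.33, neither past the threshold. The dimmer probe sets of AOX1 (-0.70), ITGA2 (-0.53), EFHD2 (-0.39) and CXCL5 (-0.58 and -0.03) kept the sign, with overlapping groups. CXCL5 and CXCL2 passed only by probe sets ending in _x_at. The count was 10 without untreated replicate 1, 19 without untreated replicate 2 (14 of the 17 among them), 8 without untreated replicate 3, 8 without BMP9 replicate 1, 9 without BMP9 replicate 2 and 8 without BMP9 replicate 3. The probe sets of POSTN (2), SEMA3G, CCL20, AOX1 and KCNMA1 passed in each of the 6 fits that left out 1 culture.

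**Figure D1:**
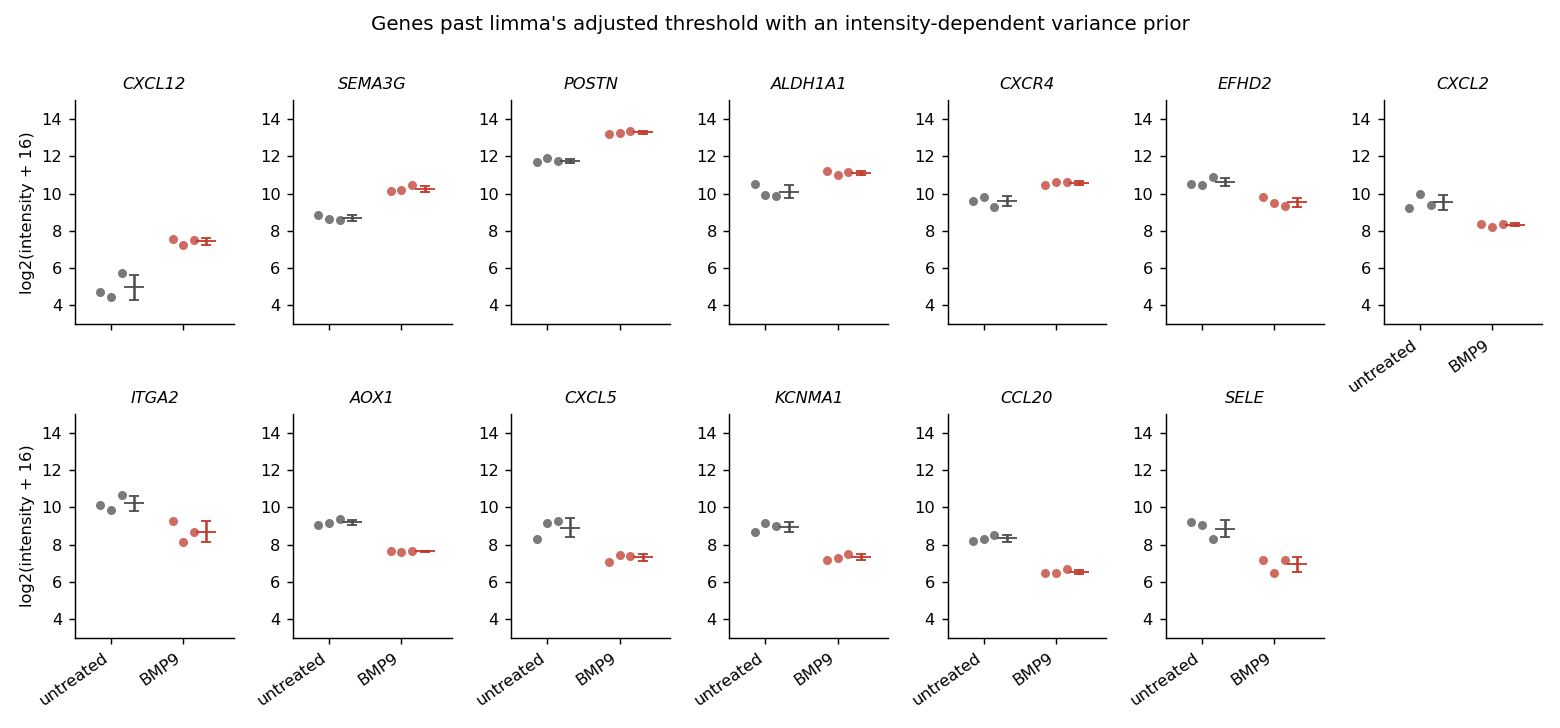
Log2(intensity + 16) of the 13 named genes past limma's adjusted threshold with an intensity-dependent variance prior, for the 3 untreated (grey) and 3 BMP9-treated (red) cultures; points are arrays, and the horizontal mark with bars is the mean ± SD (n = 3). The 3 BMP9 values of each gene lie on one side of the 3 untreated values, as for POSTN (13.27 against 11.76) and SELE (6.95 against 8.87).

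Chemokine and receptor genes were lower as a group. Of 25 measured members of the list fixed before the data were examined, 17 were lower and 8 higher with BMP9, with a median log2 fold change of -0.18 (camera, adjusted p = 0.00921; adjusted p = 0.453 with an estimated correlation). No member passed limma's test over all probe sets, while adjusted over the list alone 5 fell and 2 rose. The 5 that fell were CCL20, CXCL5 (-1.60, SE 0.30), CXCL2 (-1.22, SE 0.25), CXCL3 (-0.86, SE 0.22) and ACKR3 (-1.11, SE 0.22), a scavenging receptor for CXCL12. The 2 that rose were CXCL12 (log2 fold change 1.00, SE 0.21), which guides stem and progenitor cells, and its signalling receptor CXCR4 (10.58 ± 0.10 against 9.58 ± 0.27, SD, n = 3; log2 fold change 1.00, SE 0.22). The other CXCL12 probe set, near background in untreated cells, gave 7.44 ± 0.18 with BMP9 against 4.97 ± 0.69 (SD, n = 3). CXCL6 stood at -0.66 (SE 0.23) and CXCL1 at -0.34 (SE 0.24), neither past the threshold adjusted over the list alone. With the intensity-dependent prior, adjusted over the list alone, CXCL6 passed as well (adjusted p = 0.0489), but not over all probe sets (0.777). CXCL8, the brightest member of the list and chosen after its values were seen, did not differ (log2 fold change -0.0006, SE 0.19), so the fall did not extend to all members.

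Genes of endothelial inflammatory activation, many of them NF-kappaB targets, were also lower as a group. Of 18 measured members 13 were lower and 5 higher, with a median log2 fold change of -0.26 (camera, adjusted p = 0.00462; adjusted p = 0.453 with an estimated correlation). SELE fell when adjusted over the list alone, and no member passed over all probe sets. VCAM1, the adhesion molecule for monocytes and lymphocytes, stood at -1.02 (SE 0.33), IL6 at -0.79 (SE 0.40) and the NF-kappaB inhibitor TNFAIP3 at -0.60 (SE 0.22), while the pentraxin gene PTX3 stood at 0.34 (SE 0.20). These 4 values did not pass with 1 variance prior, while with the intensity-dependent prior, adjusted over the list alone, VCAM1 (adjusted p = 0.00596), TNFAIP3 (0.0314), PTX3 (0.0404) and LTB, a gene chosen after its values were seen (0.0404), passed beside SELE. Over all probe sets with that prior SELE passed, while VCAM1, TNFAIP3, PTX3 and LTB did not (limma, adjusted p = 0.435, 0.659, 0.747 and 0.756). In the BMP9 arrays the ratio of 3' to 5' signal of the GAPDH control probe sets, a measure of RNA integrity and labelling, was 4.95 ± 0.73 against 3.98 ± 0.38 (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give), and that of actin was 66.4 ± 11.8 against 49.6 ± 20.7 (n = 3; two-sided exact permutation p = 0.3). Over all arrays of both groups the ratio ran from 3.59 to 5.78 for GAPDH and from 30.1 to 79.4 for actin. Signal thus leaned strongly to the 3' end on every array, and whether RNA degradation or the labelling caused this was not tested. The call of the chemokine list was lost without untreated replicate 2 (adjusted p = 0.0736), BMP9 replicate 1 (0.138) or BMP9 replicate 2 (0.0696), and that of the inflammatory list without untreated replicate 1 (0.0716) or BMP9 replicate 2 (0.0788). Without probe sets whose names end in _x_at or _s_at neither list passed (adjusted p = 0.22 for both), and with the mean of a gene's probe sets the chemokine list did not (0.22). The chemokine list did not pass with the GAPDH ratio as a covariate either (adjusted p = 0.0742), although its median log2 fold change moved from -0.18 to -0.30, and with fry neither list passed (adjusted p = 0.147 for chemokines and 0.311 for inflammatory activation). Fry's other test, of change in any direction, passed for both lists (adjusted p = 0.00037 and 0.000277). It also passed for lists that camera did not call, such as BMP-SMAD targets (0.000115), and does not ask whether a list fell. Over all alternatives the adjusted p ran from 5.24e-05 to 0.453 for the chemokine list and from 1.57e-05 to 0.453 for the inflammatory list.

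**Figure D2:**
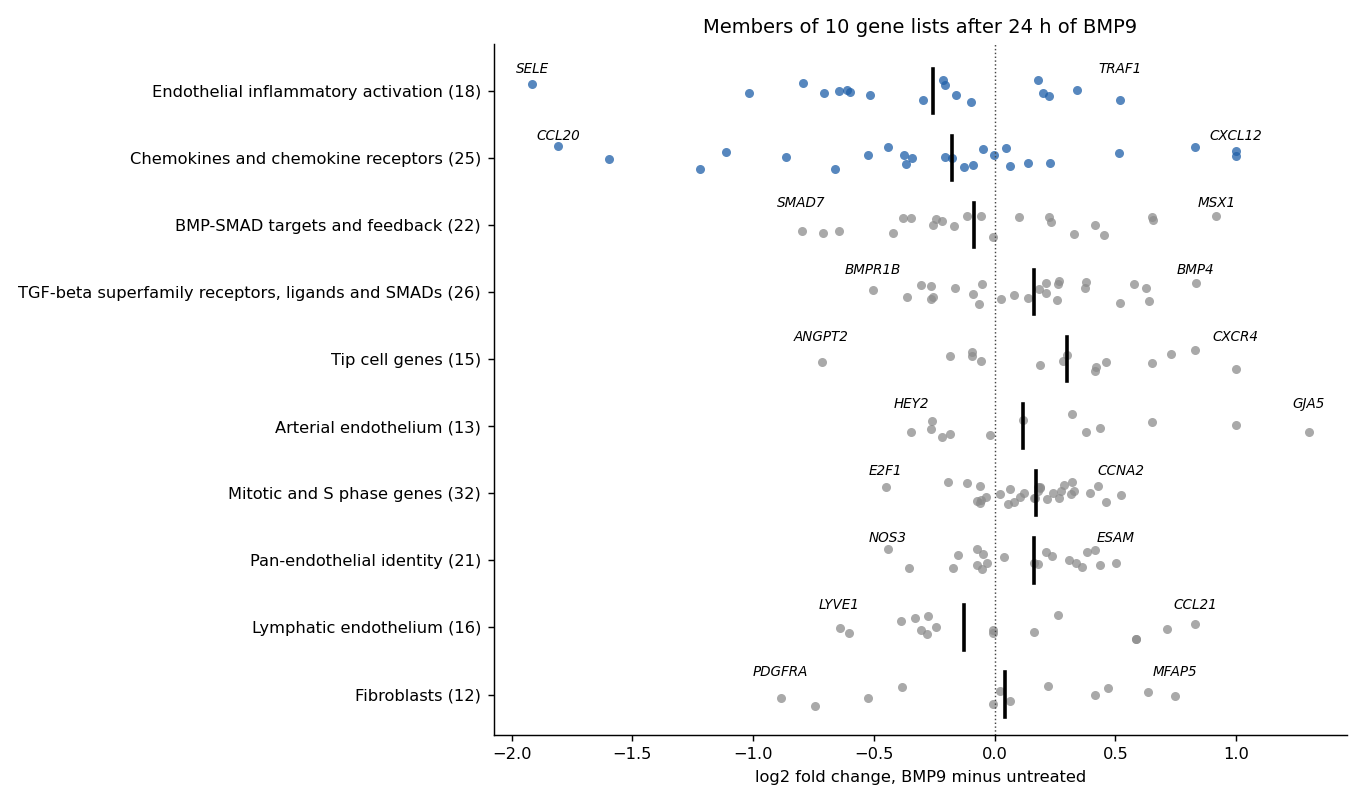
Log2 fold change, BMP9 minus untreated, of the measured members (their number in brackets) of 10 gene lists; each point is a gene, the black bar is the list's median, and blue marks the 2 lists past camera's adjusted threshold with a preset correlation (adjusted p = 0.453 for both with an estimated correlation). The medians of those lists are -0.26 for endothelial inflammatory activation and -0.18 for chemokines and chemokine receptors, and the genes at the ends of each list are named.

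None of the 22 measured BMP-SMAD targets and feedback genes passed limma's test with 1 variance prior, over all probe sets or adjusted over the list alone. With the intensity-dependent prior ID1 (lower) and MSX1 (higher) passed when adjusted over the list alone (adjusted p = 0.0168 for each), although the other probe set of MSX1, dim in both groups, was lower. Over all probe sets with that prior neither gene passed (adjusted p = 0.532 for each). The median log2 fold change was -0.09 (camera, adjusted p = 0.490), with 9 members higher and 13 lower. ID1, an inhibitor of basic helix-loop-helix factors and a direct SMAD target, was at 8.42 ± 0.17 with BMP9 against 9.13 ± 0.19 without (SD, n = 3; log2 fold change -0.71, SE 0.22). The inhibitory SMAD gene SMAD7 stood at -0.80 (SE 0.23), SMAD6 at -0.17 (SE 0.24; 0.47 without _x_at and _s_at probe sets), ID2 at -0.38 (SE 0.21) and ID3 at -0.42 (SE 0.19). TMEM100 stood at 0.66 (SE 0.22) and the netrin receptor gene UNC5B at 0.65 (SE 0.33). MSX1 stood at 0.92 (SE 0.24) by its brightest probe set, and ID4, near background in untreated cells, had overlapping groups. Of 26 measured superfamily receptors, ligands and SMADs, 16 were higher and 10 lower, none past the threshold with 1 variance prior (median 0.16; camera, adjusted p = 0.490). ENG stood at 0.63 (SE 0.26), ACVRL1 at 0.27 (SE 0.23) and BMPR2 at -0.06 (SE 0.21). The ligand genes BMP4 and INHBA, which encodes the activin A subunit, stood at 0.83 (SE 0.21) and 0.58 (SE 0.22), and passed adjusted over the list alone with the intensity-dependent prior (adjusted p = 0.00198 and 0.0138). Over all probe sets with that prior they did not pass (adjusted p = 0.123 and 0.471).

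No angiogenic or identity gene passed over all probe sets with 1 variance prior, and few passed when adjusted over a list alone. Among 15 tip cell genes 10 were higher and 5 lower, with a median log2 fold change of 0.30 (camera, adjusted p = 0.108), and CXCR4 rose when adjusted over the list alone. The basement membrane gene NID2 stood at 0.83 (SE 0.27), ESM1 at 0.46 (SE 0.19) and ANGPT2, the TIE2 ligand that destabilises vessels, at -0.72 (SE 0.22). These 3 passed in the tip cell list with the intensity-dependent prior, adjusted over the list alone (adjusted p = 0.0033, 0.022 and 0.00357). Over all probe sets with that prior they did not pass (adjusted p = 0.364, 0.694 and 0.451). Among 13 arterial genes CXCR4 rose when adjusted over the list alone (list median 0.12; adjusted p = 0.348). The connexin 40 gene GJA5 also passed there, but at a mean intensity of 5.78 in untreated cells, under the array medians, so no size is given. In the 24 genes of VEGF, PDGF and angiopoietin signalling, 16 were lower and 8 higher (median -0.11; adjusted p = 0.348), with VEGFC at -0.70 (SE 0.27), and ANGPT2 alone passed adjusted over the list alone with the intensity-dependent prior (adjusted p = 0.0171). Among 23 genes of semaphorin, netrin, ephrin and slit guidance SEMA3G rose when adjusted over the list alone (median 0.04; adjusted p = 0.457). The 21 pan-endothelial genes had a median of 0.16 (adjusted p = 0.544), with PECAM1 at 0.24 (SE 0.19) and CDH5 at -0.03 (SE 0.29). The 18 Notch pathway genes had a median of -0.10 (adjusted p = 0.530) and the 6 venous genes a median of 0.18 (adjusted p = 0.699), with no member past the threshold.

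Matrix genes differed in both directions. Of 23 basement membrane and matrix genes, BGN, the small proteoglycan biglycan, rose (9.10 ± 0.11 against 8.02 ± 0.18, SD, n = 3; log2 fold change 1.08, SE 0.21) and LAMA5, a laminin chain of vascular basement membrane, fell (-1.17, SE 0.28) when adjusted over the list alone (list median 0.08; camera, adjusted p = 0.423). Among 19 matrix proteases and inhibitors the tissue plasminogen activator gene PLAT stood at -0.95 (SE 0.25) and the protease inhibitor gene SERPINE2 at 0.74 (SE 0.21), neither past the threshold with 1 variance prior (median -0.10; adjusted p = 0.423) and both past it adjusted over the list alone with the intensity-dependent prior (adjusted p = 0.000898 for each). The 19 vasoactive and coagulation genes had a median of -0.02 (adjusted p = 0.423), and the 14 genes of endothelial-mesenchymal transition a median of 0.11 (adjusted p = 0.907). The YAP-TAZ and SRF targets, 14 measured, had a median of 0.11 (adjusted p = 0.423), with CCN2 at 0.50 (SE 0.24). With the intensity-dependent prior, adjusted over each list alone, CCN2 (adjusted p = 0.0332), NID2 and MGP among matrix genes (0.00338 and 0.0128), and PLAT and THBS1 among vasoactive genes (0.0012 and 0.00212) passed as well, MGP and THBS1 being chosen after their values were seen. Over all probe sets with that prior none of these genes passed, nor did SERPINE2 (adjusted p = 0.568 for CCN2, 0.111 for PLAT and 0.136 for SERPINE2). The YAP-TAZ and SRF list passed only among the brightest quartile of probe sets (adjusted p = 0.0496), and over all alternatives its adjusted p ran up to 0.586.

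Of 32 mitotic and S phase genes 24 were higher and 8 lower with BMP9 (median log2 fold change 0.17; camera, adjusted p = 0.108), with CCNA2 at 0.52 (SE 0.21) and TYMS at 0.46 (SE 0.21). No member passed. This list and the tip cell list did pass camera's threshold with an intensity-dependent variance prior (adjusted p = 0.00913 and 0.0101) and after quantile normalization (adjusted p = 0.0172 and 0.0371). With an estimated correlation both had an adjusted p = 0.453, and over all alternatives it ran from 0.00182 to 0.453 for the mitotic list and from 0.0101 to 0.453 for the tip cell list. The 12 cyclin D and CDK inhibitor genes had a median of 0.10 (adjusted p = 0.780). Of 25 interferon-stimulated genes 18 were lower (median -0.15; adjusted p = 0.315). In the 16 heat shock and unfolded protein response genes the stress gene DDIT3 stood at -1.16 (SE 0.46) and CHAC1 was lower, at an intensity under the array medians with BMP9, neither past the threshold (median -0.08; adjusted p = 0.348). Medians were -0.04 for 10 flow-responsive KLF genes (adjusted p = 0.457), -0.05 for 19 hypoxia and glycolysis genes (adjusted p = 0.780) and -0.01 for 12 cholesterol synthesis genes (adjusted p = 0.873). The 16 oxidative phosphorylation genes had a median of -0.07 (adjusted p = 0.653) and the 14 ribosomal protein genes a median of 0.13 (adjusted p = 0.490). Among the latter RPL27 passed adjusted over the list alone with the intensity-dependent prior (adjusted p = 0.0237), but not over all probe sets (0.536).

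Marker lists of other cells that a skin culture can hold did not pass, and none of their members did. The 16 lymphatic endothelial genes had a median log2 fold change of -0.12 (adjusted p = 0.699), the 12 fibroblast genes one of 0.04 (adjusted p = 0.780) and the 12 pericyte and smooth muscle genes one of 0.09 (adjusted p = 0.544). The 8 keratinocyte genes had a median of 0.03 (adjusted p = 0.780) and the 11 leukocyte genes a median of 0.34 (adjusted p = 0.544). RGS5, a pericyte gene, stood at 0.67 (SE 0.28), and PDGFRA, a fibroblast receptor, was lower, but at a mean intensity of 8.32 with BMP9, under the array medians, so no size is given. For the lymphatic, cholesterol synthesis and hypoxia lists the mean was above 0 (0.004, 0.02 and 0.02) where the median and camera's direction were below it. For the fibroblast list camera's direction was down with a median and a mean above 0 (mean 0.003), and for the keratinocyte list the direction and the mean (-0.002) were down with a median above 0.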

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

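Tests on the probe sets called with the intensity-dependent prior, on the brightest quartile and with the 3' to 5' ratios were chosen only after the lists and calls had been seen; the others were fixed beforehand. The count of 0 genes and 0 probe sets held under every alternative fixed beforehand except the intensity-dependent robust prior. That gave 17 probe sets and 12 genes by their brightest probe set, CXCL12 being named only by its other probe set and so not among the 12. The brightest quartile of probe sets without that prior gave 8 probe sets, or 5 when its own prior was kept and p was adjusted over 54613 tests, and 0 with the common prior. The mean over a gene's probe sets gives no value per probe set. The 2 lists became 4 with quantile normalization, 4 with an offset of 64, 4 among probe sets above the median intensity and 4 with the intensity-dependent prior, the tip cell and mitotic lists being added each time, and 5 in the brightest quartile without that prior, where the YAP-TAZ and SRF list (adjusted p = 0.0496) was added as well. They became 0 without _x_at and _s_at probe sets, 1 with the mean of a gene's probe sets, 0 with an estimated correlation, 0 with fry (adjusted p = 0.147 and 0.311 for the chemokine and inflammatory lists) and 1 with the GAPDH ratio as a covariate, and ran from 0 (without BMP9 replicate 2) to 3 (without untreated replicate 3) with 1 culture left out. Probe sets called with the intensity-dependent prior fell from 17 to 8 without robust estimation and to 11 above the median intensity, rose to 43 above the lowest quartile (all 17 among them), and ran from 8 to 19 with 1 culture left out; with the other settings they ran from 14 to 20. Filtering tests fewer probe sets, and leaving out a culture fits fewer samples; for the other differences the cause was not tested. Dim signal limits what can be seen: the median residual SD was 0.530 in the quartile of probe sets just below the median intensity and 0.233 in the brightest quartile. It did not rise steadily as intensity fell, since the dimmest quartile had 0.360.

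Whether the replicate numbers pair the cultures stays open. Same-numbered cultures correlated at 0.00526, 0.0647 and 0.0249 in their deviations, all above 0 but below the 0.1 needed of every pair. Above the median intensity they correlated at 0.00033, 0.126 and 0.0442, of which 1 passes 0.1. Of 6 cultures 4 correlated best with their own number. Falling short of 0.1 does not show that pairing is absent. With the replicate block 0 genes, 0 probe sets and 2 lists passed, and 18 probe sets with the intensity-dependent prior, so no list call changed.

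Among lists that did not pass, camera's direction turned in the following settings, given with the list's median log2 fold change there. Without _x_at and _s_at probe sets these were Notch (-0.18), cyclin D (0.073) and endothelial-mesenchymal transition (0.063). With the mean of a gene's probe sets they were VEGF, PDGF and angiopoietin signalling (0.11), fibroblasts (0.18), cholesterol synthesis (0.086) and oxidative phosphorylation (0.062). Above the median intensity it was fibroblasts (0.42), and above the lowest quartile pericytes (-0.021), keratinocytes (0.21) and endothelial-mesenchymal transition (0.066). With quantile normalization these were endothelial-mesenchymal transition (0.038), cholesterol synthesis (0.00615) and ribosomal proteins (-0.055), with median centring endothelial-mesenchymal transition (0.00232), and with the replicate block the same list (0.11). With the actin ratio as a covariate these were fibroblasts (0.16), keratinocytes (-0.00847), cyclin D (0.052), endothelial-mesenchymal transition (0.099), cholesterol synthesis (0.067) and hypoxia (0.049). With the GAPDH ratio they were Notch (-0.091), venous genes (-0.00620), keratinocytes (-0.045), endothelial-mesenchymal transition (-0.17), cholesterol synthesis (0.16) and ribosomal proteins (-0.040). In the brightest quartile it was hypoxia (0.046), and with fry, which leaves the medians as they were, fibroblasts (0.044), cholesterol synthesis (-0.012) and hypoxia (-0.046). Of named genes, CDH2 (0.00336) and PDK1 (0.26) turned with the mean of their probe sets, and MFAP5 (-0.13), MSX1 (-0.63), MYH11 (0.082) and SMAD6 (0.47) without _x_at and _s_at probe sets. The cause was not tested.

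With 1 culture left out, results whose sign, or for lists camera's direction, turned at least once ran as follows: BMPR2 -0.15 to 0.023, APLNR -0.54 to 0.00940, CDH5 -0.28 to 0.23, SMAD6 -0.28 to 0.029 and MVD -0.034 to 0.70. List medians ran from -0.00802 to 0.13 for cyclin D, -0.15 to -0.040 for lymphatic genes, -0.030 to 0.20 for ribosomal proteins, -0.23 to 0.27 for fibroblasts, -0.19 to 0.025 for oxidative phosphorylation, 0.00899 to 0.22 for venous genes, -0.034 to 0.052 for cholesterol synthesis, 0.00437 to 0.14 for endothelial-mesenchymal transition, -0.017 to 0.23 for pan-endothelial genes and -0.072 to 0.14 for keratinocytes. Of the other values of named genes, 885 with all cultures and 504 with 1 left out kept their direction and side of the threshold, and 12 passed it, all with the intensity-dependent prior. For lists 422 and 156 kept them, 11 and 1 newly passed, and 8 and 5 no longer passed.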

Other observations

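The tests of the dim-probe explanation, of co-variation, of exchanged group labels and of RNA integrity for each list by itself were chosen, or their criterion changed, only after the result was seen; the criteria for scaling, for RNA integrity of both lists together and for the other splits were written before their results were seen, although the fits with the 3' to 5' ratios were themselves chosen after the lists had been seen to be lower.

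When the dimmest quartile of probe sets was left out of the fit with the intensity-dependent prior, 43 probe sets passed limma's adjusted threshold, 22 higher and 21 lower with BMP9. The genes added there included BMP4, a ligand of the same superfamily, and BGN, which were higher, and PLAT, the scavenger receptor gene ACKR3 and the laminin gene LAMA5, which were lower. Their log2 fold changes were 0.83 (SE 0.21), 1.08 (SE 0.21), -0.95 (SE 0.25), -1.11 (SE 0.22) and -1.17 (SE 0.28), n = 3 per group.

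Chemokine and inflammatory lists were lower with BMP9. Array scaling is argued against by quantile normalization alone, under which camera's adjusted p was 0.00472 for both lists. The highest adjusted p of the 2 lists over quantile normalization and median centring was 0.0324, under median centring. Centring lowers the fold changes of all genes alike and leaves their order as it was, so it tests little here. Camera's adjusted p still moved under centring, from 0.00921 to 0.0324 for chemokines and from 0.00462 to 0.0078 for inflammatory activation. RNA integrity stays open for both lists. The highest adjusted p (camera) with the actin or the GAPDH 3' to 5' ratio as a covariate was 0.0113 for the inflammatory list. That met the criterion against RNA integrity, which was written after the result was seen. For the chemokine list, and so for the pair, it was 0.0742. The GAPDH fit cannot decide, since every BMP9 array had a higher ratio (4.49 to 5.78) than every untreated array (3.59 to 4.34). With the actin ratio, whose values overlapped between the groups, both lists passed (0.00414 and 0.0113). The median of the 43 members moved from -0.20 to -0.27 with the actin ratio and to -0.43 with the GAPDH ratio. Co-variation among members also stays open: with an estimated correlation both lists had an adjusted p of 0.453, which met the criterion as it was written before the result was seen, but that test called 0 of 20 simulated shifted lists, a condition added afterwards, so it cannot decide. Other splits of the 6 cultures also gave lists with a smaller adjusted p by camera (0.00153 and 0.00166) than the real split (0.00462). An effect of BMP9 on these genes remains a hypothesis.

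ID1, ID2, ID3 and SMAD7, textbook targets that BMP signalling raises, were lower with BMP9 by all 5 of their probe sets (2 of them for ID2), while in the same list ID4, which was dim, and SMAD6 (-0.17, SE 0.24) had overlapping groups and MSX1 stood at 0.92 (SE 0.24). None passed limma's threshold adjusted over all probe sets, and the 4 were picked because they were lower, so this is no test of the pattern. Array scaling is argued against by quantile normalization alone, under which their median was -0.55 (-0.57 as deposited), since median centring lowers all genes alike and could not have raised it. Exchanged labels of the 2 groups stay open: ENG and TMEM100, also raised by BMP9 in endothelium, were higher, the smaller difference being 0.63 for ENG, or 2.44 SE. The criterion written beforehand, over 2 SE above 0, was met and would have counted against an exchange. It was replaced by an adjusted p at or under 0.05, because 3331 of 54613 probe sets had an unadjusted p under 0.05 by limma. ENG misses the new criterion at 0.804, but no probe set could meet it, since limma's smallest adjusted p was 0.561. The new criterion thus decides nothing. Known targets differed in both directions, which does not settle the question, and a late feedback phase at 24 h was not tested.

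Calls appeared only when the variance prior could follow intensity, or among bright probe sets alone. The noise of dim probe sets entering a common prior fits this: the median residual SD just below the median intensity was 2.28 times that of the brightest quartile, and a prior from the brightest quartile alone gave 5 calls there with p adjusted over 54613 tests and 8 over 13654, where the common prior gave 0 over 13654. Above the median intensity, without a trend, no probe set passed (smallest adjusted p = 0.188). This does not show which of the 17 called probe sets respond to BMP9.

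The 6 cultures can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and 0 probe sets, and the highest other split 0 and 0, so all 10 gave as many. At an unadjusted p under 0.05 it gave 3331 probe sets, and the highest other split 3405. It gave 2 lists, as did 1 other split, so 2 of the 10 gave as many. Other splits reached a smallest adjusted p of a list (camera) of 0.00153 and 0.00166, where the real split reached only 0.00462. It gave 17 probe sets with the intensity-dependent prior against at most 5, and a correlation of 0.173 against at most 0.0871 between the log2 fold changes of the 2 brightest probe sets of 5681 genes, across genes, which are not independent replicates, and in both only 1 split, the real one, gave as much.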
